A study of Mus musculus with 12 samples.

How the data were processed

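The 12 samples are RNA libraries of fractions of inguinal adipose tissue. Per the labels' protocols, tissue of 2 mice was pooled and digested with collagenase. Debris was removed, a second spin parted the stromal vascular pellet from the mature adipocyte layer, and, per the same protocols, strand-specific libraries were made with the Universal plus mRNA-Seq kit of NuGEN. Replicates are therefore pools of 2 mice, 3 per genotype label and fraction. Per the submitters' processing notes, STAR 2.7.2a, edgeR 3.26.8 and the genome build GRCm38 were used. The counting tool and the annotation are not given in the sources used here. The deposited values are CPM, counts scaled so that each library sums to 1000000 over the genes listed. Every gene was above 0.1 CPM in at least 3 libraries, so a filter of that kind is taken to have been applied. In each library 100% of the CPM values were whole multiples of one step, within a tolerance of 0.05 read, so whole reads were recovered, 21836878 to 29434125 per library. The precision of a single value is that of these reads, and a level near 3 reads (0.102 to 0.137 CPM) is a floor for counting error only. Gene symbols came from the deposited table, and 23 of them had been turned into dates by a spreadsheet and are not named. Of all genes listed, 16489 (98.9%) matched a symbol in GENCODE mouse release 21, which gave positions, transcript lengths and GC content. Mitochondrially encoded genes had 0 members in the table, and Y-linked genes were not analysed here.

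Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust) on log2(CPM + 1). Genes at 1 CPM or more in at least 3 of the libraries fitted were tested, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The genotype labels were compared within mature adipocytes (11913 genes) and within the stromal vascular fraction (13792 genes), each with its own 6 libraries. The fractions were compared, and the difference between the genotype differences was tested, in all 12 libraries with one mean per group (14193 genes). Replicate numbers link the fractions of one pool: the deviations from the group means of the mature adipocyte and stromal vascular libraries of one genotype and number correlated at 0.169 to 0.278 in all 6 pairs, across genes. They are therefore taken as pairs, from the data. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

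Before the data were examined, 27 gene lists were fixed: mature adipocyte, preadipocyte and fibroblast progenitor, extracellular matrix, thermogenic, lipid synthesis, fatty acid oxidation, oxidative phosphorylation, cholesterol synthesis, cell cycle, inflammatory signalling, interferon response, immediate early and heat shock, unfolded protein response, histone H3K4 methylation, other genes that escape X inactivation, X-linked neighbours of Kdm5c, germline, macrophage, lymphocyte, endothelial, pericyte and smooth muscle, mammary epithelium, skeletal muscle, Schwann cell, red blood cell, cytosolic ribosomal protein and mitochondrially encoded genes. Lists with at least 5 tested members were tested with camera of limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera asks whether a list is shifted against the other genes. An estimated correlation and fry, which asks whether the genes of a list move one way on balance, were the alternatives. Counts adjusted over the list alone use limma's p of its members.

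The rule for genes to name was fixed with the lists. It took Kdm5c first. It then took up to 12 genes per direction with the largest log2 difference among those past the threshold with no overlap between the groups, or, where fewer than 5 passed in a direction, those that passed and the 5 with the smallest p. Up to 4 members of each shifted list and 2 of the others, by p, followed. For the fractions it took 10 genes per direction and 3 members of each marker list, and for the difference between fractions the 3 with the smallest p where none passed. Of these genes, some are left out of the text.

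On data simulated with 200 changed genes, limma recovered 75.8% of 2-fold and 93.8% of 4-fold changes in the mature adipocyte comparison (3.55% false calls) and 74.0% and 97.0% in the stromal vascular comparison (4.42%). It recovered 79.4% and 99.0% between fractions (6.49%), and 43.0% and 85.7% for the difference between fractions (8.63%). The simulated genes varied independently, around 1 mean per gene over all libraries of a comparison. Genes that move together were not simulated, nor were fractions that differ in most genes (12466 of 14193 in the data). All recovery and false-call rates given here, those of DESeq2 included, hold for that setting and may differ in the data. Alternatives were another pseudocount (0.25), other filters (none, or a mean of at least 5 CPM), median-of-ratios and quantile scaling, and a replicate block. Others were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, eBayes without trend and robust, all 12 libraries in a genotype fit, and leaving out each library in turn. Chosen after seeing the data were the removal of Rn45s, the removal of a smooth trend on transcript length and GC content from each library, and the list test of the difference between fractions with its alternatives. Reads of near-identical genes such as Rps4l and Rps4x may have been split between them, and single members of the ribosomal protein list are uncertain for the same reason.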

Results

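Gene expression was measured by RNA sequencing in 12 libraries from inguinal white adipose tissue, a fat depot under the skin, of female C57BL/6 mice. Tissue pooled from 2 mice was digested with collagenase and spun. Mature adipocytes were taken from the floating layer, and the stromal vascular cells, a mixture of progenitor, vascular and immune cells, from the pellet. Each fraction gave 3 libraries labelled Kdm5c+/– and 3 labelled Kdm5c+/+ (wild type), so that there were 4 groups of 3. A library held 21836878 to 29434125 reads over the genes listed. Levels are in CPM, counts scaled to a total of 1000000 per library, and 3 reads came to between 0.102 and 0.137 CPM. The comparisons ask how the fractions differ, which genes differ between the genotype labels within each fraction, and whether that difference is unlike in the fractions. CPM is given as mean ± SD, and log2 differences as the estimate ± SE.

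Kdm5c, an X-linked gene that escapes X inactivation and encodes a demethylase of histone H3 lysine 4, lies on the plus strand of chromosome X from 152233020 to 152274535 in GRCm38. In mature adipocyte libraries labelled Kdm5c+/–, its level was 158, 190.3 and 158 CPM, against 179, 174 and 180.0 CPM in wild type. In stromal vascular libraries labelled Kdm5c+/–, it was 194, 190.4 and 175 CPM, against 188, 185 and 180.1 CPM in wild type. The group means were 169.0 ± 18.4 and 177.7 ± 2.99 CPM in mature adipocytes (n = 3 each, ratio 0.948, 95% interval 0.810 to 1.11). They were 186.5 ± 9.89 and 184.6 ± 4.09 CPM in the stromal vascular fraction (n = 3 each, ratio 1.01, 95% interval 0.895 to 1.14). A ratio of 0.5, which the loss of 1 of a pair of equally active copies would give, lies outside both intervals. The libraries are therefore called by their labels throughout. Every direction between genotypes follows labels that the level of Kdm5c does not bear out. The labels do not say which part of the gene was removed. Reads from outside a removed part would still count, so the level over the whole gene does not check a partial deletion.

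**Figure D1:**
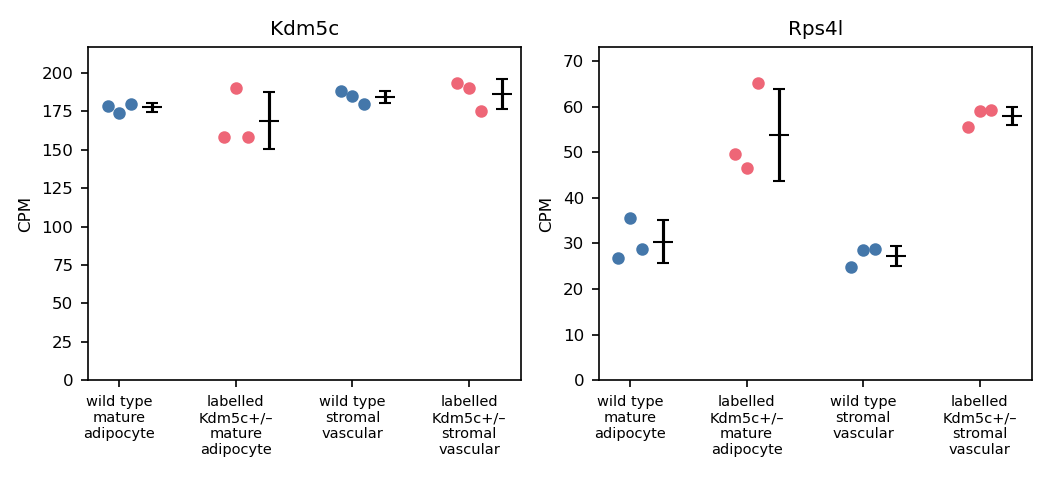
Level of Kdm5c and of Rps4l in CPM in each of the 12 libraries, by fraction and genotype label, with each point 1 library and the black mark the mean ± SD of 3. Kdm5c lay between 158 and 194 CPM in all 4 groups, and Rps4l had means of 53.8 and 57.9 CPM in the groups labelled Kdm5c+/– against 30.4 and 27.3 CPM in wild type.

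The mature adipocyte libraries were rich in the genes of fat cells. Adipoq, the adipocyte hormone adiponectin, averaged 4331 ± 226 CPM in mature adipocyte and 99.7 ± 55.6 CPM in stromal vascular libraries (n = 6 each), a log2 difference of 5.62 ± 0.27. Other genes with large differences in this direction were Adrb3, the beta-3 adrenergic receptor (5.75 ± 0.32), Slc7a10 (5.66), and Cfd, the secreted protease adipsin (5.60). Glb1l2 (5.57), Plin1, a coat protein of lipid droplets (5.56), Tmem45b (5.56), Hp, haptoglobin (5.52), Retn, the hormone resistin (5.47), and Cdsn (5.46) followed. In the stromal vascular libraries the largest differences on the log2(CPM + 1) scale, which shrinks those of genes near 0 in mature adipocytes, were for Vwf, the endothelial von Willebrand factor (-6.82 ± 0.16, 506.2 CPM against 3.62 CPM in mature adipocytes) and the matrix gene Fbn1 (-6.56). After them came Fndc1 (-6.54), Mmp2 (-6.52), Dcn (-6.49), the progenitor marker Pdgfra (-6.48), Plvap (-6.44), Aebp1 (-6.34), Lama2 (-6.32) and Lum (-6.32). All of these passed with adjusted p of at most 9.51e-08. In total, 12466 of 14193 genes passed in limma, 4072 higher in mature adipocytes and 8394 higher in the stromal vascular fraction. That balance changed with the scaling. The 10 most abundant genes took 15.7% to 19.3% of the CPM in mature adipocyte libraries and 5.77% to 8.41% in stromal vascular libraries. The median of all genes moved up by a log2 of 0.37 with median-of-ratios scaling, 0.54 with quantile normalization, 0.47 with edgeR and 0.39 with DESeq2. The split between higher in mature adipocytes and higher in the stromal vascular fraction then became 5721 to 6550, 6678 to 5542, 6063 to 6145 and 5768 to 6530.

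By list, the counts were the same adjusted over the list alone as over all genes tested. Of 24 mature adipocyte genes, 22 were higher in mature adipocytes, among them Cebpa (4.10), a transcription factor of fat cell differentiation, the insulin-responsive glucose transporter Slc2a4 (3.70) and the hormone-sensitive lipase Lipe (3.67). Also higher there were 22 of 23 lipid synthesis, 20 of 21 fatty acid oxidation, 72 of 73 oxidative phosphorylation and 19 of 24 cholesterol synthesis genes. Of 18 thermogenic genes, 12 were higher in mature adipocytes and 5 in the stromal vascular fraction. Higher in the stromal vascular fraction were 14 of 14 macrophage genes, such as Mrc1 (-5.86) and the complement genes C1qa (-5.64) and C1qb (-5.50). The same held for 18 of 18 lymphocyte genes, such as the B cell gene Cd79a (-4.03) and Cd4 (-3.72), and for 12 of 12 endothelial genes, such as the receptors Flt1 (-5.04) and Eng (-4.95). So were 20 of 23 preadipocyte and fibroblast progenitor genes, with Cd34 at -5.99 and Gpc3 at -5.67. Of 38 extracellular matrix genes 32 were higher there, as were 9 of 11 pericyte and smooth muscle genes, with Notch3 at -5.67 and Pdgfrb at -5.58. The inguinal depot holds the mammary gland, and 12 of 13 mammary epithelium genes, with Krt19 at -5.43 and Epcam at -4.08, were higher there too. Other lists with most members higher in the stromal vascular fraction were Schwann cell (7 of 8, Sox10 at -3.53), skeletal muscle (6 of 8), cell cycle (28 of 31), interferon response (16 of 18) and inflammatory signalling (12 of 18). Last came cytosolic ribosomal protein genes (66 of 79, median -0.93, and -0.39 to -0.62 under the other scalings), and the red blood cell gene Alas2 (-4.85). Sizes moved with the method for other lists as well. With edgeR the medians went from -3.26 to -6.51 for mammary, -3.46 to -5.77 for lymphocyte, -1.77 to -3.92 for inflammatory and -1.36 to -4.01 for skeletal muscle genes. With quantile normalization they came to -0.81 for cell cycle (from -2.01), -0.54 for interferon response (from -1.37), -1.01 for inflammatory and -0.33 for skeletal muscle genes, and to 1.80 for thermogenic (from 1.15) and 1.84 for cholesterol synthesis genes (from 1.20). Of the histone H3K4 methylation regulators, 14 of 18 were higher in the stromal vascular fraction, with a median of -0.48 that came to -0.01 with edgeR. The medians of the immediate early and heat shock genes (8 of 19 higher in each fraction), the unfolded protein response genes (7 of 13 higher in the stromal vascular fraction), the other genes that escape X inactivation (6 of 10) and the X-linked neighbours of Kdm5c (6 of 9) changed sign with the scaling. Among germline genes, Sycp3, which encodes a protein of the synaptonemal complex of meiosis, was the 1 gene tested, and it was higher in mature adipocytes (3.32, and 5.37 with edgeR).

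**Figure D2:**
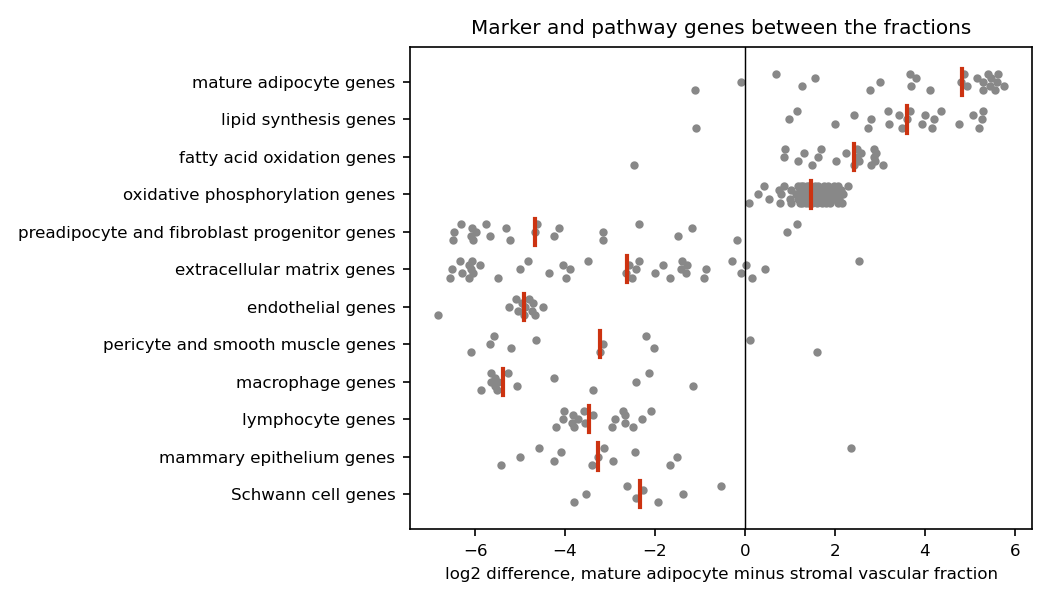
Log2 difference in CPM between mature adipocyte and stromal vascular libraries (mature adipocyte minus stromal vascular, 6 libraries each) for the members of 12 lists, with each dot 1 gene and the red bar the median of the list. On this log2(CPM + 1) scale the medians run from 4.84 for mature adipocyte genes to -5.38 for macrophage genes, while with edgeR mammary epithelium genes were lowest (-6.51).

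In mature adipocytes, the genes with the smallest p between the genotype labels included a receptor of lipolysis, a subunit of the respiratory chain and genes of the circadian clock. Adrb3 averaged 959.6 ± 67.1 CPM in the libraries labelled Kdm5c+/– and 539.4 ± 33.5 CPM in wild type (n = 3 each, log2 difference 0.83 ± 0.11). Dbp, a transcription factor driven by the clock, averaged 26.6 ± 4.32 against 9.14 ± 2.67 CPM (1.46 ± 0.20). Ndufa1, a subunit of respiratory complex I, averaged 84.5 ± 4.39 against 55.9 ± 4.04 CPM (0.59 ± 0.08). Higher with them were Myh14, a non-muscle myosin (0.91 ± 0.13), and Phyhd1 (0.63 ± 0.09). Lower were the clock repressor Cry1 (-1.33 ± 0.20), the scavenging chemokine receptor Ackr3 (-1.23 ± 0.18), and Itm2a (-1.11 ± 0.17). Also lower were Skil, a repressor in the SMAD pathway (-0.71 ± 0.09), and the transcriptional repressor Trps1 (-0.62 ± 0.08). For each of these 10 genes the 3 libraries of one label lay outside the 3 of the other, an arrangement that chance gives in 10% of genes. As the genes were picked by smallest p, which favours that arrangement, it adds no support. The adjusted p of each was 0.273. None of 11913 genes passed in limma, where 1737 had an unadjusted p under 0.05 (664 higher, 1073 lower, 596 expected by chance). The edgeR test called 0 with 1755 unadjusted. DESeq2 called 250 genes, 125 in each direction, and made 21.1% false calls on data simulated for this comparison. Without the library labelled Kdm5c+/– replicate 3, limma called 3 genes (Gbp11, Mycl and Sox4, named after their values were seen). With all 12 libraries in the fit it called Synm, which was lower.

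Of 21 lists tested by camera in mature adipocytes, 6 were shifted upward and 4 downward. None was called with an estimated correlation, for which each adjusted p is given. That correlation had a median of 0.346 over the lists, with 0.612 for oxidative phosphorylation and 0.791 for endothelial genes, against the preset 0.01. A p at the preset value can therefore be far too small where genes move together. For mature adipocyte and cytosolic ribosomal protein genes the estimate was -0.038 and 0.0045, under the preset value. Their calls were lost as well, so a correlation above the preset value does not account for those losses. Of the 10 splits of the 6 libraries into 3 and 3, 6 shifted as many lists as the real split. No member of any list passed over all genes tested. Oxidative phosphorylation genes were shifted upward (68 of 72 members higher, median 0.18, adjusted p = 3.81e-17, and adjusted p = 0.453 with an estimated correlation). Adjusted over the list alone, 4 passed, Ndufa1 and the cytochrome c oxidase subunits Cox5b (0.46), Cox6a1 (0.48) and Cox6c (0.39). Fatty acid oxidation genes were shifted upward too (18 of 21 higher, median 0.19, adjusted p = 6.90e-06, and adjusted p = 0.453 with an estimated correlation). None (0) passed adjusted over the list alone, and values were 0.42 for Pex11a, 0.33 for Eci1 and 0.31 for Acadl. Mature adipocyte genes were shifted upward (16 of 24 higher, median 0.14, adjusted p = 0.00341, and adjusted p = 0.237 with an estimated correlation). Adrb3 alone passed adjusted over the list alone, and Cidec, a lipid droplet protein, had 0.58 ± 0.19, Acsl1 0.56 ± 0.20 and Fabp4 0.38 ± 0.15. Lipid synthesis genes were shifted upward (17 of 23 higher, median 0.19, adjusted p = 0.0184, and adjusted p = 0.699 with an estimated correlation). Here too 0 passed adjusted over the list alone, with values of 1.30 ± 0.69 for Acacb, 0.43 for Mogat1 and 0.42 for Dgat1. Interferon response genes were shifted upward (15 of 18 higher, median 0.37, adjusted p = 3.61e-05, and adjusted p = 0.453 with an estimated correlation). Zbp1 (0.92 ± 0.19) and Irf7 (1.07 ± 0.26) passed adjusted over the list alone, and Ifi44 had 1.05 and Oas1a 0.84. Cytosolic ribosomal protein genes were shifted upward (57 of 77 higher, median 0.12, adjusted p = 1.54e-06, and adjusted p = 0.0802 with an estimated correlation). Adjusted over the list alone 1 passed, Rps26 (0.45 ± 0.08), beside values of 0.80 ± 0.16 for Rps4l and 0.48 for Rpl23.

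The lists shifted downward in mature adipocytes were endothelial, pericyte and smooth muscle, extracellular matrix and progenitor genes. Markers of the endothelial, pericyte and progenitor lists were mostly scarce there. In wild-type libraries the median endothelial, pericyte and progenitor gene stood at 3.84%, 3.56% and 2.30% of its stromal vascular level. Extracellular matrix genes were not scarce, with a median of 178 CPM in mature adipocyte and 1256 CPM in stromal vascular libraries. Lox stood at 229, 304 and 260 CPM in wild-type mature adipocyte libraries. In wild-type stromal vascular libraries it was at 223, 201 and 215 CPM. A change in the stromal vascular cells carried over was not parted from a change in adipocytes. Endothelial genes were lower in 12 of 12 members (median -0.72, adjusted p = 7.50e-06, and adjusted p = 0.453 with an estimated correlation). Of them 8 passed adjusted over the list alone, with Kdr at -0.86 ± 0.20, Flt1 at -0.70 ± 0.14, Cdh5 at -0.79 and Tek at -0.87. Pericyte and smooth muscle genes were lower in 9 of 10 (median -0.93, adjusted p = 0.00499, and adjusted p = 0.453 with an estimated correlation). Of these 4 passed adjusted over the list alone, with Notch3 at -1.04 ± 0.27, Kcnj8 at -0.94, Pdgfrb at -0.93 and Rgs5 at -0.93. Extracellular matrix genes were lower in 32 of 37 (median -0.35, adjusted p = 0.00158, and adjusted p = 0.651 with an estimated correlation). Bgn was at -1.38 ± 0.49, Timp3 at -1.01 ± 0.31 and Lox at -0.70 ± 0.20. Progenitor genes were lower in 20 of 21 (median -0.34, adjusted p = 0.00728, and adjusted p = 0.599 with an estimated correlation). Cd34 was at -0.70, Lum at -0.62 and Dcn at -0.60. Both of these lists had 0 members adjusted over the list alone. Macrophage genes were lower in 11 of 12 (median -0.44, Mrc1 at -0.87) and did not pass (adjusted p = 0.0848). By the mean over this list, 0 libraries labelled Kdm5c+/– lay below all wild-type libraries. Wild-type replicate 2 stood apart, with C1qa at 10.6 CPM against 4.42 and 4.64 CPM in replicates 1 and 3. In the libraries labelled Kdm5c+/– C1qa was at 4.07, 4.48 and 3.80 CPM. Schwann cell genes were lower in 7 of 7 (median -0.21, S100b at -1.24, Cdh19 at -0.79) and did not pass either (adjusted p = 0.0686). In these libraries the ribosomal RNA precursor Rn45s stood at 5805 ± 1635 CPM in those labelled Kdm5c+/– and 4065 ± 299 CPM in wild type. The thermogenic (8 of 16 higher, median 0.01, Cox8b at 0.78), cholesterol synthesis (10 of 24, -0.09) and cell cycle lists (6 of 17, -0.14, Cdc6 at -0.80) were not shifted, with adjusted p of 0.536, 0.819 and 0.141. The same was true of the inflammatory signalling (3 of 11, -0.21), immediate early and heat shock (14 of 19, 0.04) and unfolded protein response lists (8 of 13, 0.10), with adjusted p of 0.170, 0.162 and 0.0686. Nor were the histone H3K4 methylation regulators (6 of 18, -0.02, Kdm1b at -0.31, Kdm5a at -0.28, adjusted p = 0.536). Unshifted too were the other genes that escape X inactivation (4 of 10, adjusted p = 0.941, with a median of -0.06 and a test direction upward) and the X-linked neighbours of Kdm5c (7 of 8, 0.07, adjusted p = 0.0686). Adjusted over the list alone, 1 unfolded protein response gene, the chaperone Calr (0.63 ± 0.13), and 1 neighbour, Tspyl2 (0.28 ± 0.07), passed, and 0 in the other lists named here. The median of the H3K4 regulators turned to 0.03 with median-of-ratios and 0.02 with quantile scaling, and that of the escape genes to 0.01 with quantile scaling. With too few members for a test, Sycp3 had 0.92 ± 0.22, the epithelial Trp63 0.10, and the muscle genes Acta1 and Tnnc2 -0.58 and -0.30. Fry called 2 lists, mature adipocyte and ribosomal protein genes, each with adjusted p = 0.00354.

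Some list calls in mature adipocytes changed with 1 library or with the processing. Without wild-type replicate 2, lipid synthesis genes had a median of -0.11 (adjusted p = 0.524) and progenitor genes -0.15 (adjusted p = 0.0780). Without replicate 1 labelled Kdm5c+/– lipid synthesis genes had 0.01 (adjusted p = 0.230). With quantile normalization the mature adipocyte call (median 0.11, adjusted p = 0.226) and the lipid synthesis call (median 0.18, adjusted p = 0.196) were lost, with medians close to those before. With a trend on transcript length and GC content removed the ribosomal call (median 0.07, adjusted p = 0.118) and the lipid synthesis call (median 0.23, adjusted p = 0.0932) were lost. In that fit inflammatory signalling (adjusted p = 0.0475), neighbours of Kdm5c (0.0323), macrophage (0.0154) and Schwann cell genes (0.0485) were gained, and Schwann cell genes also with a mean CPM of at least 5 (0.0377). Lists gained by leaving out 1 library were macrophage genes without wild-type replicate 1 (adjusted p = 0.00245) or 3 (0.0226). Both of these fits keep wild-type replicate 2, where Lyz2 stood at 27.6 CPM against 9.92 and 10.5 CPM in replicates 1 and 3. Schwann cell genes were gained without wild-type replicate 1 (0.0154) or replicate 1 labelled Kdm5c+/– (0.0402), and thermogenic genes without wild-type replicate 1 (0.0232). Immediate early genes were gained without replicate 1 labelled Kdm5c+/– (0.0362) or wild-type replicate 2 (0.00608). The same went for unfolded protein response genes without replicate 3 labelled Kdm5c+/– (0.0314) or wild-type replicate 2 (0.0493). Cholesterol synthesis genes were gained without wild-type replicate 2 (0.00608), and the neighbours of Kdm5c without replicate 1 labelled Kdm5c+/– (0.0362).

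**Figure D3:**
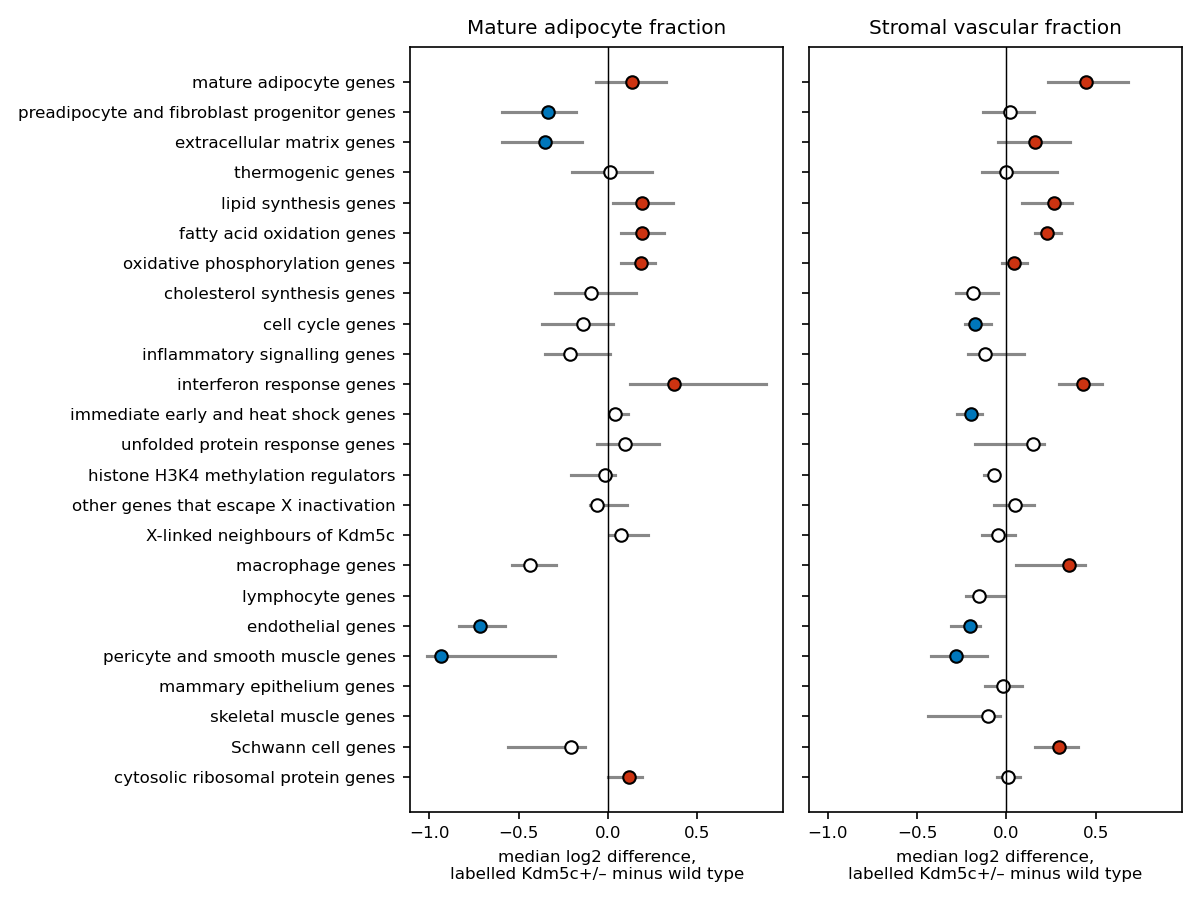
Median log2 difference in CPM (libraries labelled Kdm5c+/– minus wild type) of each list in mature adipocytes and in the stromal vascular fraction, with the dot the median over genes and the line the quartiles. Filled dots mark lists with an adjusted p under 0.05 by camera at the preset correlation, red upward and blue downward. They are 10 lists in mature adipocytes and 12 in the stromal vascular fraction, and none of them passed with an estimated correlation.

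In the stromal vascular fraction, the 1 gene that passed between the genotype labels was Rps4l, on the plus strand of chromosome 6 from 148354656 to 148355598 in GRCm38. It is annotated as a transcribed processed pseudogene and is nearly identical to Rps4x, the gene of a protein of the small ribosomal subunit. Its level rose from 27.3 ± 2.23 CPM in wild type to 57.9 ± 2.05 CPM in the libraries labelled Kdm5c+/– (n = 3 each, log2 difference 1.06 ± 0.08, 2.09-fold, adjusted p = 0.0347 in limma). It was higher in 3 of 3 libraries than in any wild-type library. Next by p, and not past the test, were Igsf21 (1.10 ± 0.14), the aminopeptidase Xpnpep2 (1.14 ± 0.18), the zinc finger gene Zfp783 (0.77 ± 0.15) and Tex14, known from germ cell bridges (1.10 ± 0.21). Lower and not past the test were Clca5 (-1.60 ± 0.18, 16.9 to 4.91 CPM), Rasa4, which encodes a Ras GTPase-activating protein (-0.70 ± 0.08), and the Wnt modulator Dkk2 (-1.03 ± 0.14). With them stood the endothelial proteoglycan gene Esm1 (-1.19 ± 0.18) and Olfm2 (-0.61 ± 0.10), and the adjusted p of these genes was 0.187 or more. Of 13792 genes tested, 1043 had an unadjusted p under 0.05 (285 higher, 758 lower, 690 expected by chance). The edgeR test called 1, and DESeq2 called 53 with 23.4% false calls on data simulated for this comparison. The call of Rps4l was lost in 9 of 18 alternatives (log2 0.99 to 1.13, adjusted p 8.11e-19 to 0.345). Among them were the fit without trend and robust variance (adjusted p = 0.108) and the removal of a trend on length and GC content (0.0798). So were each of the 6 fits without 1 library, replicates 1, 2 and 3 labelled Kdm5c+/– (0.314, 0.173 and 0.141) and wild-type replicates 1, 2 and 3 (0.176, 0.259 and 0.118). With all 12 libraries in the fit Clca5, Dkk2 and Igsf21 passed as well, and reads may be shared between Rps4l and Rps4x, so its level is uncertain.

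Of 24 lists tested by camera in the stromal vascular fraction, 8 were shifted upward and 4 downward. None was called with an estimated correlation (adjusted p from 0.710) or by fry (adjusted p from 0.709). The estimated correlation had a median of 0.458 over the lists, against the preset 0.01. Of the 10 splits of these 6 libraries, 3 shifted as many lists as the real split. Apart from Rps4l, no member passed over all genes tested. Interferon response genes were shifted upward (17 of 18 higher, median 0.43, adjusted p = 1.98e-10, and adjusted p = 0.710 with an estimated correlation). Zbp1 was at 0.79 ± 0.25, Oas1a at 0.74, Mx1 at 0.56 and Bst2 at 0.31. Mature adipocyte genes were shifted upward (22 of 24 higher, median 0.45, adjusted p = 1.42e-07, and adjusted p = 0.710 with an estimated correlation). Adrb3 was at 1.32 ± 0.59, Cidec at 1.11 ± 0.45, Lipe at 0.47 and Lpl at 0.31. Adipoq, which marks adipocytes left in this fraction, stood at 129.7 ± 64.0 CPM in libraries labelled Kdm5c+/– and 69.8 ± 30.9 CPM in wild type. By replicate it was at 165, 169 and 55.8 CPM against 105, 45.4 and 59.5 CPM. Replicate 3 labelled Kdm5c+/– thus lay within the wild-type range. A change in the adipocytes left was not parted from a change in stromal vascular cells, for this list or the fatty acid oxidation, lipid synthesis and oxidative phosphorylation lists. Fatty acid oxidation genes were shifted upward (20 of 21 higher, median 0.23, adjusted p = 1.52e-09, and adjusted p = 0.710 with an estimated correlation), in which Cpt1a had 0.40 and Pex11a 0.59. So were lipid synthesis genes (19 of 22, 0.26, adjusted p = 0.00725, and adjusted p = 0.711 with an estimated correlation), in which Dgat1 had 0.28 and Scd2 -0.47. Oxidative phosphorylation genes were shifted with them (45 of 72, 0.04, adjusted p = 0.00198, and adjusted p = 0.711 with an estimated correlation), with Ndufc2 at 0.33. Macrophage genes were shifted upward (13 of 14 higher, median 0.35, adjusted p = 2.52e-05, and adjusted p = 0.710 with an estimated correlation). C1qc was at 0.46 ± 0.15, Itgam at 0.45 and C1qa at 0.42. So were extracellular matrix genes (27 of 38, 0.16, adjusted p = 0.000322, and adjusted p = 0.710 with an estimated correlation). The collagens Col1a1 and Col1a2 were at 0.56 ± 0.20 and 0.57 ± 0.20, and Nid2 at -0.51. Schwann cell genes were shifted upward (8 of 8, 0.29, adjusted p = 0.00565, and adjusted p = 0.710 with an estimated correlation). S100b was at 0.47 and Mbp at 0.43. Each of these 8 lists had 0 members adjusted over the list alone.

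Immediate early and heat shock genes were shifted downward in the stromal vascular fraction (17 of 19 lower, median -0.20, adjusted p = 0.000305, and adjusted p = 0.710 with an estimated correlation). Among them were Ier3, Nr4a1 and Egr1 each at -0.37. Pericyte and smooth muscle genes were too (9 of 11, -0.28, adjusted p = 0.00347, and adjusted p = 0.710 with an estimated correlation). Among the latter, 2 passed adjusted over the list alone, Mcam (-0.39 ± 0.08) and Notch3 (-0.45 ± 0.12), and Kcnj8 had -0.80. Endothelial genes were lower in 11 of 12 (median -0.20, adjusted p = 0.00557, and adjusted p = 0.710 with an estimated correlation), with Kdr at -0.34 and Tie1 at -0.32. Cell cycle genes were lower in 29 of 31 (-0.17, adjusted p = 0.0151, and adjusted p = 0.711 with an estimated correlation), with Rrm2 at -0.44 and Foxm1 at -0.38. The immediate early, endothelial and cell cycle lists had 0 members adjusted over the list alone. Rn45s stood at 15712 ± 5844 CPM in the stromal vascular libraries labelled Kdm5c+/– and 6654 ± 91.7 CPM in wild type, beside all of these shifts. Progenitor genes were not shifted (14 of 23 higher, median 0.02 and mean -0.02, adjusted p = 0.853), but Dlk1, a marker of preadipocytes, passed adjusted over the list alone (-0.83 ± 0.16). In inflammatory signalling (6 of 17 higher, median -0.12, adjusted p = 0.206), Nos2 (-0.81 ± 0.16) and Ccl3 (-0.80 ± 0.19) passed adjusted over the list alone. In the ribosomal protein list (43 of 79 higher, 0.01, adjusted p = 0.147) Rps4l did. The thermogenic (7 of 15 higher, median -0.0022, adjusted p = 0.634), cholesterol synthesis (6 of 24, -0.19, 0.254) and unfolded protein response lists (7 of 13, 0.15, 0.206) were not shifted. Neither were the histone H3K4 methylation (2 of 18, -0.07, 0.0701, Setd1b at -0.30), escape (6 of 10, 0.05, 0.289, Xist at 0.25) and neighbour lists (3 of 8, -0.05, 0.548, Iqsec2 at -0.21). These 6 lists had 0 members adjusted over the list alone. Nor were the lymphocyte (4 of 18, -0.16, adjusted p = 0.857), mammary epithelium (6 of 13, -0.02, 0.703) and skeletal muscle lists (1 of 7, -0.10, 0.237), also with 0 adjusted over the list alone. The test direction of the thermogenic, lymphocyte and mammary lists was upward, against their medians, and the thermogenic and mammary medians turned positive under both other scalings. No germline gene was high enough to test, and the red blood cell gene Alas2 had 0.45.

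Single libraries weighed on the stromal vascular lists as well. Without replicate 1 labelled Kdm5c+/–, the lipid synthesis (adjusted p = 0.496) and oxidative phosphorylation calls (median -0.02, 0.689) were lost. Without its replicate 2, the cell cycle (0.776), endothelial (0.163) and Schwann cell calls (0.393) were lost. In that fit lymphocyte (median 0.39, 0.000454), skeletal muscle (-0.45, 0.0296) and mammary genes (-0.41, 0.00959) were called. Without its replicate 3, the extracellular matrix call was lost (0.412) and cholesterol synthesis (0.0144), inflammatory (0.00960), mammary (median 0.47, 0.00577) and ribosomal protein genes (0.00151) were called. Without wild-type replicate 1 the oxidative phosphorylation (median -0.0020, 0.253), cell cycle (0.0660) and Schwann cell calls (0.105) were lost. Without wild-type replicate 2, lipid synthesis genes had a median of -0.04 (0.852), the cell cycle call was lost (0.390) and cholesterol synthesis genes were called (0.00122). Without wild-type replicate 3 the pericyte call was lost (0.119), and H3K4 regulators (0.000553) and lymphocyte genes (median -0.69, 0.0193) were called. The oxidative phosphorylation call was also lost with the length and GC trend removed (0.0574).

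The difference between the fractions in the effect of the genotype label was tested gene by gene in all 12 libraries. The smallest p belonged to the mRNA-decapping gene Dcp2 (-0.66 ± 0.11, mature adipocyte minus stromal vascular), Abhd14b (0.49 ± 0.09) and the matrix protease gene Adamts4 (-0.82 ± 0.15), each with adjusted p = 0.445. None of 14193 genes passed in limma, where 1267 had an unadjusted p under 0.05 (710 expected by chance). The edgeR test called 0 with 1427 unadjusted, and DESeq2 called 65. Without mature adipocyte replicate 3 labelled Kdm5c+/–, limma called 7 genes, Col1a1, Cyp2d22, Hmga2-ps1, Ncoa7, Rps6ka3, Slfn5 and St6gal1.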

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

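The list tests of the difference between the fractions, the removal of a trend on length and GC content, and the test on carry-over of stromal vascular cells were chosen after the results were seen. In 9 of 24 lists, the shift between the genotype labels differed between mature adipocytes and the stromal vascular fraction by camera at the preset correlation, with the same 9 when the fractions of a pool were a block. None passed with an estimated correlation (adjusted p from 0.872) or by fry (from 0.648). Each value is the median log2 difference in mature adipocytes minus that in the stromal vascular fraction, taken gene by gene. The shift was lower in mature adipocytes for macrophage genes (-0.80, adjusted p = 0.000970), Schwann cell genes (-0.52, 0.00280) and endothelial genes (-0.52, 0.000242). It was also lower there for extracellular matrix genes (-0.45, 2.01e-06), mature adipocyte genes (-0.38, 0.0420) and progenitor genes (-0.37, 0.0227). Mature adipocyte genes rose in both fractions, with medians of 0.14 in mature adipocytes and 0.45 in the stromal vascular fraction. Among macrophage genes, C1qa stood at 10.6 CPM in wild-type mature adipocyte replicate 2 against 4.42 and 4.64 CPM in replicates 1 and 3. The macrophage call was kept without that library. The shift was higher in mature adipocytes for immediate early and heat shock genes (0.25, 0.000469), oxidative phosphorylation genes (0.12, 2.01e-06) and ribosomal protein genes (0.093, 0.00183). The mature adipocyte call was lost in 8 of the 12 fits without 1 library. Those were the fits without mature adipocyte replicates 1 and 3 labelled Kdm5c+/– (adjusted p = 0.0541 and 0.150) or wild-type 1 and 3 (0.103 and 0.0658). They were also those without stromal vascular replicates 1 and 2 labelled Kdm5c+/– (0.380 and 0.484) or wild-type 2 and 3 (0.497 and 0.0636). That call was also lost with a pseudocount of 0.25 (0.0568) and with Rn45s left out (0.0549). The progenitor call was lost without wild-type mature adipocyte replicate 2 (0.230), stromal vascular replicate 3 labelled Kdm5c+/– (0.164) or wild-type stromal vascular replicate 2 (0.284). The Schwann cell call was lost without stromal vascular replicate 2 labelled Kdm5c+/– (0.0609), and the ribosomal call without its replicate 3 (0.164). Gained were the neighbours of Kdm5c without mature adipocyte replicate 1 (0.0373) or stromal vascular replicate 2 (0.0199) labelled Kdm5c+/– or wild-type mature adipocyte replicate 2 (0.0446), and with a mean CPM of at least 5 (0.0433). Also gained were cholesterol synthesis without mature adipocyte replicate 2 labelled Kdm5c+/– (0.0342), mammary genes without stromal vascular replicate 2 labelled Kdm5c+/– (0.00420), and fatty acid oxidation without its replicate 3 (0.00161). Lymphocyte genes were gained without stromal vascular replicate 2 labelled Kdm5c+/– (-0.47, 0.0255) or wild-type stromal vascular replicate 3 (0.65, 0.00692). Of the 10 splits of the 6 pools into 3 and 3, 4 shifted as many lists as the real split, which shifted 9, and the highest of the others shifted 11. For single genes the real split called 0, so that 10 of the 10 splits call as many whatever the data, and the highest of the others called 4. With 10 splits no share under 0.05 can be reached.

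By camera at the preset correlation, vascular markers were lower and oxidative phosphorylation genes higher in the mature adipocyte libraries labelled Kdm5c+/–, and with an estimated correlation neither was called (adjusted p = 0.453 for each list). Across 11828 genes the log2 difference went with transcript length (Spearman -0.30) and GC content (0.13), though genes are not independent replicates, and the median transcript was 1186 nt for oxidative phosphorylation and 3758 nt for vascular genes. Removing that trend took the vascular median from -0.81 to -0.74, past the bound set before (-0.40). The SE over libraries, here and below, is that of per-library medians and was not part of the bound. By those medians the vascular difference was -0.68 with an SE of 0.27, past the bound by little more than that SE. These values argue against the trend as the whole cause of the vascular shift. The oxidative phosphorylation median went from 0.18 to 0.13, 71.7% of it, with the camera call kept at the preset correlation (adjusted p = 2.27e-07) and absent with an estimated one (0.607), but it passed the bound set before (0.092) by less than its SE over libraries (0.074), so that a length or GC trend and a shift of these genes cannot be told apart. A carry-over of fewer stromal vascular cells of every kind cannot be told apart from a loss of vascular markers alone, since the lead of the vascular score over the progenitor and macrophage score differed between the genotype labels by -0.35 with an SE of 0.30, and the genotype label, with Kdm5c not lower, stays open as untested.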

How the results depend on the processing

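Leaving out Rn45s, removing the trend on length and GC content, and the alternatives of the list test between fractions were chosen after seeing the data. For the fractions, 9848 to 14190 genes passed under the alternatives (12201 to 12435 without 1 library). With the pools as a replicate block 12503 passed, 12366 of them shared with the unblocked calls. With that block, 0 genes and the same 9 lists passed for the difference between fractions. Same-numbered libraries of the genotype labels were not taken as pairs. Their deviations correlated at -0.03 to 0.34 in mature adipocytes and -0.28 to 0.18 in the stromal vascular fraction. The highest values were both for replicate 1, and its 0.34 lay above those of the fraction pairs (0.169 to 0.278). A link between the genotype labels in replicate 1 is therefore not excluded. With their number as a replicate block, 0 genes passed in mature adipocytes and 0 in the stromal vascular fraction. In that fit 12 and 13 lists were shifted, adding macrophage and Schwann cell genes in the former and cholesterol synthesis genes in the latter. In mature adipocytes, 0 genes passed except with DESeq2 (250), all 12 libraries (1) and without 1 library (0 to 3). In the stromal vascular fraction, Rps4l was the 1 gene except with DESeq2 (53), all 12 libraries (4), eBayes without trend and robust (0), the replicate block (0), the length and GC trend removed (0) and without 1 library (0 in each). With the trend removed, Rps4l had a log2 of 1.08 ± 0.09 against 1.06 ± 0.08 before, so that the call ended although the estimate did not fall. For the difference between fractions, 0 genes passed except with DESeq2 (65) and without 1 library (0 to 7). Lists shifted numbered 0 with an estimated correlation and 2 by fry in mature adipocytes, 0 and 0 in the stromal vascular fraction, and 0 and 0 for the difference between fractions. Without 1 library they numbered 10 to 13, 9 to 15 and 7 to 10, and under the other alternatives 8 to 12, 11 to 13 and 8 to 10. List shifts turned direction in the test without 1 library for lipid synthesis genes in mature adipocytes (-0.11 to 0.42, lowest without wild-type replicate 2) and in the stromal vascular fraction (-0.036 to 0.48, lowest without wild-type replicate 2). They did so in the latter for mammary (-0.41 to 0.47) and lymphocyte genes (-0.69 to 0.39), and for lymphocyte genes in the difference between fractions (-0.47 to 0.65). The oxidative phosphorylation median in the stromal vascular fraction also went below 0, to -0.02 and -0.0020, without replicate 1 labelled Kdm5c+/– or wild-type replicate 1. Of list values under an alternative, 250 in mature adipocytes and 287 in the stromal vascular fraction kept their side of the threshold, and the direction of the test where called, while some lists that were not called changed sign. With the direction of the test kept, 24 and 36 of the others lost the call and 18 and 9 gained one. A further 1 and 3 turned direction. Of these, lipid synthesis genes lost the call in each fraction, and mammary and lymphocyte genes gained one in the stromal vascular fraction. For the difference between fractions 413 kept their side of the threshold, and with the direction kept 33 lost the call and 8 gained one. There 1 more turned direction and gained a call, lymphocyte genes without stromal vascular replicate 2 labelled Kdm5c+/–. Among named genes, Rps4l lost its call as above and Clca5, Dkk2 and Igsf21 gained one with all 12 libraries, and 8 values of genes that were not called (Trp63, Kdm5c, Fcer2a and Cd22) changed sign without 1 library. The cause of these changes was not tested. Depth limits single genes near 3 reads (0.102 to 0.137 CPM).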

Other observations

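The overlap between the fractions, the clock gene list with its tests, and the tests on Rps4l were chosen after the results they address were seen. Of 11526 genes tested in both fractions, 33 were higher and 143 lower in the libraries labelled Kdm5c+/– at an unadjusted p under 0.05 in each fraction, where independent lists would give 12.2 and 59.4. In all, 29 went opposite ways, where independent lists would give 55.9. Same-numbered fractions are taken to share their mice, so the lists are not independent, and no test of the excess was made. Genes with small p in both fractions, named after their values were seen, were Zfp783 (0.66 ± 0.11 in mature adipocytes, 0.77 ± 0.15 in the stromal vascular fraction), Oas2, an enzyme of the antiviral response (1.31 and 0.83), and Synm, an intermediate filament gene (-0.96 and -0.40). Others were the surface glycoprotein gene Cd200 (-1.02 and -0.54), the transcription factor Gata2 (-0.67 and -0.36) and the protocadherin Pcdh17 (-0.92 and -0.66). None of them passed over all genes in limma with the 6 libraries of a fraction. Synm passed in mature adipocytes with all 12 libraries in the fit.

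Sycp3 stood at 19.4 ± 4.87 CPM in mature adipocyte libraries labelled Kdm5c+/– and 9.68 ± 2.01 CPM in wild type, and at 0.618 ± 0.361 and 0.330 ± 0.0527 CPM in the stromal vascular fraction (n = 3 each). Ucp1, the uncoupling protein of thermogenic fat, was at 0.707 ± 0.881 and 1.20 ± 1.86 CPM in mature adipocytes. In stromal vascular libraries the epithelial keratin gene Krt8 ran from 13.1 to 66.4 CPM and the B cell gene Cd79a from 8.75 to 39.7 CPM, with both genotype labels across the range.

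Of 16 clock genes, in a list written after Dbp and Cry1 were seen, 15 were tested in mature adipocytes, and 8 passed adjusted over the clock genes alone, 0 over all genes and 0 in the stromal vascular fraction. Dbp (1.46), Nr1d2 (0.61) and Nr1d1 (0.56) were higher in mature adipocyte libraries labelled Kdm5c+/–, and Arntl (-1.46 ± 0.33), Cry1 (-1.33), Npas2 (-0.84), Clock (-0.42) and Cry2 (-0.31) lower, while the stromal vascular values were -0.04 for Dbp, -0.29 for Arntl, 0.05 for Cry1 and -0.07 for Clock, and Per1 (0.42 in mature adipocytes, 0.30 in the stromal vascular fraction) and Per2 (0.33 and 0.58) went one way in both. The shift differed between the fractions for 6 of the 16 genes adjusted over the clock genes (the same 6 with the pools as a block). They were Dbp, Nr1d1, Arntl, Npas2, Clock and Cry1. For these 6 that argues against tissue collected at another time of day with both fractions shifted alike. The bound, written after the values were seen, asked for most of the 16 and was not met. For the other clock genes a like shift cannot be told apart from a change in adipocytes alone. Among them, in pool 2 labelled Kdm5c+/–, Per1 (263 and 205 CPM) and Per2 (53.6 and 76.1 CPM) stood above every other library of the fraction in both. Less carry-over of stromal vascular RNA is argued against by its size, since the highest median share of a marker list in wild-type mature adipocytes was 3.84%, and losing all of it would change Arntl by -0.088 against the measured -1.46. The time of collection and the genotype label stay open, and the labels give no time.

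Rps4l was higher in libraries labelled Kdm5c+/– in both fractions, by 1.06 ± 0.08 in the stromal vascular fraction and 0.80 ± 0.16 in mature adipocytes, where it did not pass. A rise of reads shared with Rps4x is argued against by Rps4x itself, at 0.044 ± 0.08 (95% interval up to 0.24) in the stromal vascular fraction and -0.11 (up to 0.09) in mature adipocytes. A variant that moves reads from Rps4x to Rps4l read for read is argued against too, since Rps4x would have to fall by -0.25 in the stromal vascular fraction and -0.51 in mature adipocytes, below its 95% intervals (from -0.15 and -0.30). A region of another haplotype around Rps4l cannot be told apart from a change of Rps4l alone, since 0 of 18 genes within 2 Mb had an unadjusted p under 0.05 in both fractions in one direction but 0.27 would be so at the share of the other genes (1.52%), and of the 18 genes 6 were higher in both, 8 lower in both and 4 opposite, with Mettl20 at 0.45 in mature adipocytes and 0.38 in the stromal vascular fraction, and Stk38l at -0.25 and -0.24. That region, a variant of Rps4l that brings in reads not counted before, and the genotype label stay open.

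Other splits of the libraries were counted. In mature adipocytes, the real split of the 6 libraries into 3 and 3 called 0 genes, so that 10 of the 10 splits call as many whatever the data and that count decides nothing, and the highest of the others called 19. That split had replicates 1 and 2 labelled Kdm5c+/– and wild-type replicate 1 on one side. For lists there, 6 of 10 splits shifted as many as the real split, which shifted 10, and the highest of the others 12. In the stromal vascular fraction, 1 of the 10 splits, the real one, called 1 gene and the highest of the others 0. For lists there, 3 of 10 shifted as many lists as the real split, which shifted 12, and the highest of the others 14. With 10 splits no share under 0.05 can be reached. Between the fractions, the real split alone, 1 of 100 drawn of 462, called as many genes as itself (12391 in a fit with 2 groups, highest of the others 7687). Likewise 1 of the 32 splits that part every pool did (highest of the others 7700). Each is the lowest share its set of splits can give, so chance is unlikely, though not excluded, for this count.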
